A study of Mus musculus with 2 samples.

How the data were processed

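The series compares the lungs of mouse pups that received the Hedgehog-blocking antibody 5E1 with those of pups that received control IgG, by droplet single-cell RNA sequencing. Per the labels, the pups carried a Gli1 allele with tamoxifen-inducible Cre and a tdTomato reporter, tamoxifen was given at postnatal day 1, antibody at day 3, and lungs were taken at day 6. Also per the labels, the lungs of 3 pups per condition were pooled and about 20000 cells were loaded, which gives 2 libraries, 1 per condition. Groups were taken from the treatment label of each library. The question of each comparison, the gene lists, the cell type markers and the alternative settings given first below were fixed before the data were examined.

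The deposited matrices hold raw counts of UMIs per gene and cell barcode, made by the authors with Cell Ranger 3.1.1 and the mm10 genome per the submitters' processing notes, although the headers of the matrices give another software version. These headers give the matrices as whole-number counts, and no normalization by the authors is recorded in them. Reporter sequences are among the 29004 features, so the authors had added them to the reference. Settings of the cell calling and of the alignment are not given in the sources used here. The authors also deposited a table of annotated cells that names the iCellR package and gives each cell a library and 1 of 23 clusters, without cell type names. The names in its header are shifted by 1 column from the middle of the table on, so the cluster and library columns were identified from their values, and the library given for each cell equals the prefix of its barcode. From the values, the authors kept barcodes with at least 500 genes and at most 10% mitochondrial UMIs, 13509 of 15021 in the IgG library and 9454 of 10519 in the 5E1 library. Kept barcodes reached 6966 and 6967 genes and those left out 7231 and 7662, so an upper limit may have been used too. The 1512 and 1065 barcodes left out, with medians of 819 and 894 UMIs, were not analysed here.

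Cells kept by the authors entered every comparison, with 77436890 UMIs in the IgG and 58890639 in the 5E1 library and medians of 1804 and 1786.5 genes per cell. Each authors' cluster was named after the fixed marker list with most members among its 10 leading genes by fold and called "like" that type. Clusters 3 and 10, led by markers of several types, kept their numbers, and the result was 18 classes. This was not applied alike, since clusters 2 and 16 were named although 2 leading genes of each are markers of another type. Clusters 12 and 14 were named from 1 leading marker each, Pdgfra and Macf1, and Pdgfra is also compared below. A class was compared in its share of cells only where none of its 10 leading genes differed by over 2-fold between the libraries. Class names rest on these rebuilt markers and not on names given by the authors.

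UMIs were summed per library and class and scaled to the total of the class (CPM). Each sum has an exact 95% Poisson interval, each ratio of sums an exact conditional binomial interval, and each share of cells an exact Clopper-Pearson interval. Ratios of cell shares were given the same conditional interval as ratios of sums. It treats numbers of cells as Poisson counts, so it is not exact for shares and is too wide where shares are large. All of them cover counting error only. With 1 library per condition no test, p-value or count of changed genes was made, since cells are not replicates. Where a sum was 0, a floor of 3 counts was used for bounds. For each gene list the median log2 ratio (5E1 over IgG, 0.5 UMI added to each sum) was taken over members with at least 20 UMIs in both libraries together. The interval of a list median comes from 1000 Poisson redraws of the sums. Its percentile among 10000 random lists of the same size, matched on expression in 20 bins, describes these libraries only. Shares of cells with a UMI of a gene, or with at least 2 UMIs of the G2 and M phase list, were taken after thinning each cell to 1000 UMIs and leaving out shallower cells.

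A fixed rule sets which genes may be named, and which of them the text prints was in part chosen after their values were seen. In each class these are the Hedgehog targets (1 member of that list is not reported here) and the PDGF ligands and receptors with at least 20 UMIs. In the alveolar myofibroblast-like and matrix fibroblast-like classes they are also the 10 genes with the highest and the 10 with the lowest log2 ratio among those with at least 200 UMIs in both libraries together and at least 50 CPM in 1 of them. In other classes of at least 300 cells per library the rule takes the 5 highest and 5 lowest, of which the text names some. The ranking left out mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and predicted genes, and genes whose CPM in the class was in both libraries under 5% of that in the class with the highest CPM, which can be free RNA. Of sex-linked genes it left out only Xist, Tsix, Ddx3y, Eif2s3y, Uty and Kdm5d. Other genes of the sex chromosomes could be ranked, such as Adgrg2 on chromosome X. For lists the rule takes 2 to 4 members with most UMIs or the largest ratio, and for some lists the text names fewer or none. Of the features 28676 have their identifier in the mouse annotation used for coordinates (GENCODE, mm10 assembly), and 62 symbols belong to several identifiers.

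Doublets were scored in each library by the method of Scrublet, written anew, with 2 simulated doublets per cell, an expected rate of 6%, 30 principal components and 2000 variable genes. The threshold was the minimum between both modes of the simulated scores. This called 564 cells (4.17%) of the IgG and 262 (2.77%) of the 5E1 library, which were kept in the main values and left out in an alternative. Of the simulated doublets 41.3% and 32.2% lay above the threshold, so part of the real ones can remain. Cells were also clustered anew with 20 neighbours and the Leiden method at resolution 1, which gave 30 clusters. The class named from these markers was the authors' one for 92.5% of alveolar myofibroblast-like, 92.6% of matrix fibroblast-like and 95.7% of endothelial-like cells, but for 25.5% of NK-like cells and 10.4% of cluster 3.

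The intervals were run on simulated Poisson counts drawn from the totals and means of the real classes, with 200 genes changed. The intervals assume such counts, so the simulation checks their computation only. Variation between cells was not simulated. For the alveolar myofibroblast-like class, with 12668 genes, the 95% interval held the true ratio for 95.8% of unchanged genes, 92% of genes changed 2-fold and 92% of genes changed 0.25-fold. For the matrix fibroblast-like class, with 12439 genes, these were 95.8%, 97% and 100%. The alternatives fixed at the start were scaling by the median ratio of genes with at least 100 UMIs, the mean over cells, cells with at least 1000 UMIs and under 10% mitochondrial UMIs, leaving out doublets, thinning, a list minimum of 100 UMIs or none, 5 UMIs added, own clusters, and other thresholds for cycling cells. Alternatives chosen after seeing the data weighted the clusters of a class alike, kept only 5E1 cells with an Xist and no Y-linked UMI, kept only cells with a reporter UMI, or left out the cell of each library with most UMIs of a gene. The computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.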

Results

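Lung cells of mouse pups were profiled by droplet single-cell RNA sequencing with the 10x Genomics 3' kit after blockade of Hedgehog ligands. The pups carried a tamoxifen-inducible Cre recombinase at the Gli1 locus and a tdTomato reporter, so that cells with Hedgehog pathway activity could be labelled. Tamoxifen was given at postnatal day 1, the ligand-blocking antibody 5E1 or control IgG at day 3, and lungs were taken at day 6, the period in which alveolar septa form. Each of the 2 conditions gave 1 library, made from the pooled lungs of 3 pups. The control IgG library held 13509 annotated cells and 77436890 UMIs (unique molecular identifiers, each counting 1 transcript molecule), with a median of 4541 UMIs per cell. The 5E1 library held 9454 annotated cells and 58890639 UMIs, with a median of 4636 per cell. With 1 library per condition no difference below has a replicate check. Intervals cover counting error only and are exact 95% intervals, except those of list medians and of ratios of cell shares. Higher and lower refer to these 2 libraries.

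The first comparison asked which cell classes made up the lung in each condition. Mesenchymal cells made up 51.4% (interval 50.5 to 52.2%) of the IgG library and 38.3% (37.3 to 39.3%) of the 5E1 library. Endothelial-like cells made up 9.57% (9.08 to 10.1%) and 13.9% (13.2 to 14.6%). AT1-like cells, the flat cells of the gas exchange surface, made up 2.12% (1.89 to 2.38%) and 4.69% (4.27 to 5.13%), a ratio of 2.21 (1.90 to 2.57), while AT2-like cells, which make surfactant, were at 5.15% (4.79 to 5.54%) and 5.36% (4.92 to 5.84%). Neutrophil-like cells were at 1.90% and 4.8%, and alveolar macrophage-like cells at 7.54% and 10.6%. Pericyte-like cells, at 3.15% (2.87 to 3.46%) and 3.43% (3.07 to 3.81%), and mesothelial-like cells, at 1.25% (1.07 to 1.45%) and 1.2% (0.986 to 1.44%), differed by less than the counting error as shares of all cells. Among non-immune cells alone, endothelial-like cells were at 13.5% and 21.4%, AT1-like cells at 3.00% and 7.22%, AT2-like cells at 7.28% and 8.27% and pericyte-like cells at 4.46% and 5.28%, a ratio of 1.18 (1.02 to 1.37). Of mesenchymal cells, pericyte-like cells made up 6.14% and 8.95%, a ratio of 1.46 (1.26 to 1.69), and mesothelial-like cells 2.44% and 3.12%. Shares are not compared for alveolar myofibroblast-like, matrix fibroblast-like, adventitial fibroblast-like, smooth muscle-like, monocyte-like, dendritic-like or NK-like cells or for cluster 3, because genes that define these classes differed over 2-fold between the libraries. All shares also depend on how well each cell type survived the enzymatic digestion.

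The transcriptional targets of the Hedgehog pathway were examined next, as a check of the labels and as the direct readout of ligand blockade. Gli1, Ptch1 and Hhip were lower in the 5E1 library in both large fibroblast classes. Ptch1, the Hedgehog receptor and itself a target, stood at 79.0 CPM (UMIs of the gene scaled to all UMIs of the class; 74.4 to 83.7) in alveolar myofibroblast-like cells of the IgG library and at 9.62 CPM (7.44 to 12.2) in those of the 5E1 library, an 8.21-fold difference (6.40 to 10.7). Hhip, a decoy receptor induced by the pathway, stood at 133 CPM (127 to 139) and 19.97 CPM (16.8 to 23.6) in the same class. In matrix fibroblast-like cells Hhip was at 222 CPM (213 to 231) and 11.3 CPM (8.46 to 14.7), a 19.7-fold difference (15.1 to 26.3), and Ptch1 at 101 CPM (95.5 to 107) and 18.8 CPM (15.1 to 23.1). Gli1, the pathway's transcription factor, gave 155 and 3 UMIs in alveolar myofibroblast-like cells, 25-fold (8.39 to 122) lower in 5E1, and 124 and 4 UMIs in matrix fibroblast-like cells, 13.6-fold (5.17 to 50.6) lower. Per the genotype label 1 of the 2 Gli1 alleles carries the Cre insertion in the pups of both libraries. The median log2 ratio of the target list was -3.73 (-4.02 to -3.15) in alveolar myofibroblast-like cells, or -2.88 with sums of 0 at the floor of 3 counts and -2.50 with cells thinned to 1000 UMIs, and -3.10 in matrix fibroblast-like cells, below all of 10000 random lists of matched expression in each case.

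The depth of the difference varied between mesenchymal classes. In adventitial fibroblast-like cells Ptch1 was 2.41-fold (1.92 to 3.04) and Hhip 2.10-fold (1.75 to 2.53) lower in the 5E1 library, while the interval of Gli1, at 20.7 CPM and 14.9 CPM, included no difference. Smooth muscle-like cells had Hhip at 156 CPM and 29.7 CPM and Ptch1 at 32.0 CPM and 8.82 CPM. They join clusters 16 and 22, of which cluster 16 held 27.6% and 14.6% of the class, and the target list median of -2.21 came to -1.64 with both clusters weighted alike. Mesothelial-like cells had Ptch1 at 77.1 CPM and 25.7 CPM and Hhip at 210.5 CPM and 82.7 CPM. In pericyte-like cells Ptch1, at 30.9 CPM (23.8 to 39.4) and 25.8 CPM (18.6 to 34.9), differed by less than the counting error, while Hhip gave 24 UMIs, or 11.4 CPM (7.31 to 17), in the IgG and 0 UMIs in the 5E1 library, at least 6.19-fold lower with the 0 at the floor of 3 counts. B cell-like cells, which should lack these genes, had Ptch1 at 11.7 CPM (6.66 to 18.9) and 8.15 CPM (4.75 to 13). Hhip there was at 16 CPM (10.0 to 24.3) and 0.959 CPM (0.116 to 3.46). These levels were taken as a background, and free RNA as its source was not tested. The log2 ratio of Ptch1 in B cell-like cells was -0.52, against -3.03 in alveolar myofibroblast-like and -2.42 in matrix fibroblast-like cells. Free RNA from those classes may therefore not account for the Ptch1 background. Ptch1 in alveolar myofibroblast-like cells of the 5E1 library lay within the counting error of that background, as did Hhip in pericyte-like cells of each library.

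The share of cells with a Ptch1 UMI, after each cell was thinned to 1000 UMIs, was 7.29% (6.22 to 8.49%) of 2098 alveolar myofibroblast-like cells of the IgG library and 0.999% (0.500 to 1.78%) of 1101 of the 5E1 library, with 10 and 3 shallower cells left out. Unthinned, the shares were 37.9% and 5.71%, at median depths of 6084 and 5593 UMIs. B cell-like cells gave 0.800% and 0.939% thinned and 3.95% and 3.76% unthinned, at median depths of 2498.5 and 3325 UMIs. For Hhip in matrix fibroblast-like cells the thinned shares were 19.4% (17.8 to 21.1%) and 1.37% (0.753 to 2.29%), against 1.87% and 0 of 426 cells (0 to 0.862%) in the B cell-like class. Thinning left out 15 and 13 matrix fibroblast-like and 5 and 0 B cell-like cells. Unthinned, the Hhip shares were 49.6% and 4.17%, at median depths of 4483.5 and 4426 UMIs, and 5.79% and 0.469% in B cell-like cells. Per the annotation of the mm10 assembly, Gli1 (ENSMUSG00000025407) lies on chromosome 10 from 127329882 to 127341974 on the minus strand, Ptch1 (ENSMUSG00000021466) on chromosome 13 from 63508328 to 63573598 on the minus strand and Hhip (ENSMUSG00000064325) on chromosome 8 from 79965851 to 80058006 on the minus strand.

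**Figure D1:**
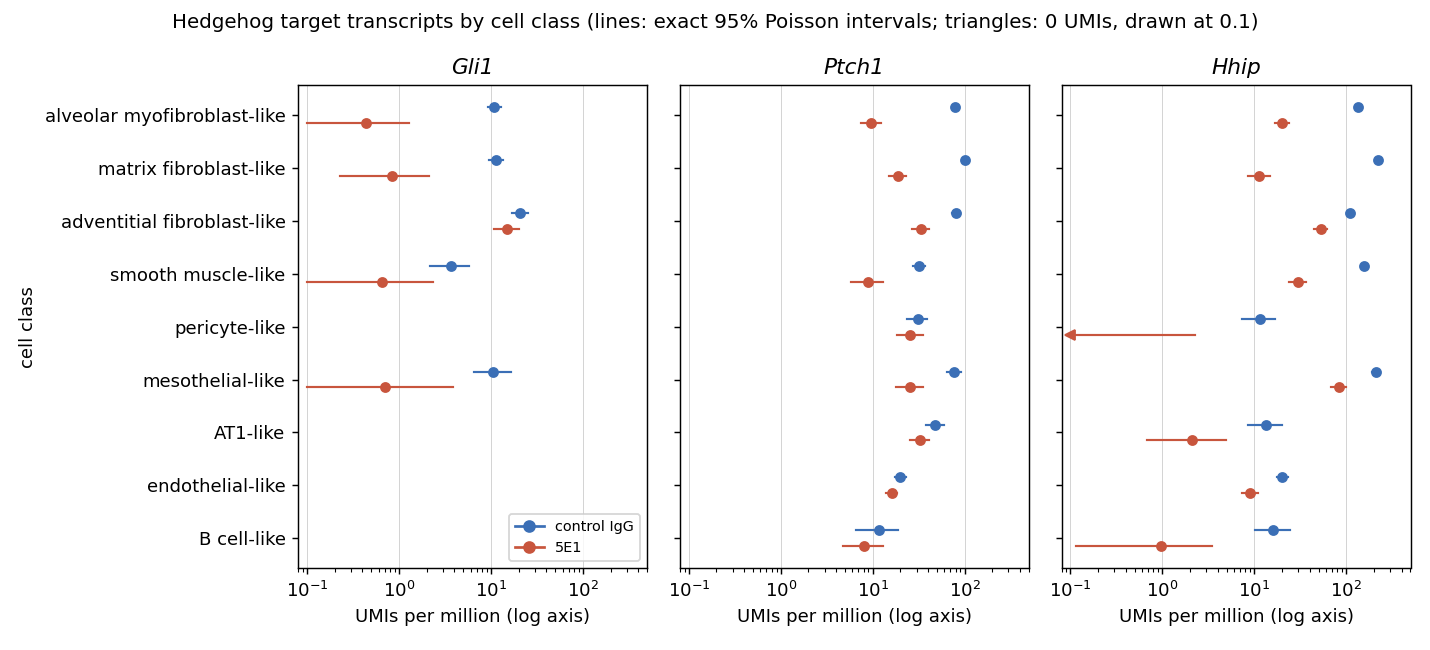
CPM of 3 Hedgehog targets (log axis) in 9 cell classes of the IgG (blue) and 5E1 (red) libraries, with exact 95% Poisson intervals as lines, triangles for 0 UMIs and no point where both libraries together held under 20 UMIs. Ptch1 and Hhip of the 5E1 library sit far below the IgG library in both large fibroblast classes and closer to it in adventitial fibroblast-like cells, where Ptch1 was at 80.2 CPM and 33.3 CPM.

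The series title names platelet-derived growth factor (PDGF) signalling in septum formation, so its ligands and receptors were compared in each class. Pdgfra and Pdgfrl were higher in the 5E1 library in both large fibroblast classes. However, Pdgfra in alveolar myofibroblast-like cells depended on which of their clusters and which of the 5E1 cells were counted. In alveolar myofibroblast-like cells Pdgfra, the receptor these cells need to form septa, was at 120 CPM (114 to 126) in the IgG and 150 CPM (141 to 159) in the 5E1 library, a ratio of 1.25 (1.15 to 1.35). Pdgfrb, the receptor typical of pericytes, had a ratio of 1.68 (1.52 to 1.84) there and Pdgfrl, a receptor-like gene, 1.76 (1.63 to 1.91). Pdgfra is also a leading gene of cluster 23, which held 23.4% of the class in the IgG and 50.0% in the 5E1 library, and of cluster 12, which held 30.4% and 15.2%. Its ratio was 1.06 (0.922 to 1.21) within cluster 12, 0.869 (0.652 to 1.14) within cluster 21 and 1.2 (1.07 to 1.35) within cluster 23. With female 5E1 cells only, the log2 ratio of Pdgfra in the class was 0.01, against 0.32 with all cells, and those of Pdgfrb and Pdgfrl were 0.31 and 0.41, against 0.75 and 0.82. The female cells were 220 of the 1104 5E1 cells of the class, and these ratios have no interval here. Such cells stem from a part of the pooled pups, so a dependence on sex and one on pup cannot be separated. In matrix fibroblast-like cells Pdgfra had a ratio of 1.45 (1.22 to 1.71) and Pdgfrl of 1.70 (1.49 to 1.94), while that of Pdgfrb, 1.22 (0.899 to 1.64), included no difference. Among the 7 genes of the list, 4 were higher and 3 lower in alveolar myofibroblast-like cells, with a median log2 ratio of 0.25 (0.07 to 0.44) at percentile 98.9 of random lists matched on expression. All 5 measured members were higher in matrix fibroblast-like cells, with a median of 0.53 (0.23 to 0.71) at percentile 99.5. Pericyte-like cells carried most Pdgfrb, at 814 CPM (776 to 854) and 983 CPM (936 to 1032). Adventitial fibroblast-like cells had Pdgfra at 88.5 CPM (80.3 to 97.4) and 88.4 CPM (77.9 to 99.97).

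The ligand Pdgfa was at the same level in its main source, the AT1-like class, with 882 CPM (838 to 928) in the IgG and 882 CPM (845 to 920) in the 5E1 library. AT2-like cells had Pdgfa at 146 CPM (135 to 157) and 188 CPM (175 to 201), a ratio of 1.29 (1.16 to 1.42). Smooth muscle-like cells, a further source, had Pdgfa at 134 CPM (124 to 145) and 164 CPM (150 to 179). Pdgfb, the endothelial ligand, was at 79.3 CPM (73.9 to 84.8) and 74.4 CPM (69.6 to 79.5) in endothelial-like cells. Pdgfra lies on chromosome 5 from 75152292 to 75198215 on the plus strand, Pdgfrb on chromosome 18 from 61045150 to 61085061 on the plus strand and Pdgfa on chromosome 5 from 138976014 to 138997370 on the minus strand. The share of cells with a Pdgfra UMI at 1000 UMIs was 9.10% (7.91 to 10.4%) and 12.1% (10.2 to 14.2%) in alveolar myofibroblast-like cells, against 0 of 375 and 0.235% of B cell-like cells, and 41.5% and 46.9% unthinned. The PDGF median of alveolar myofibroblast-like cells came to 0.53 over members with at least 100 UMIs.

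**Figure D2:**
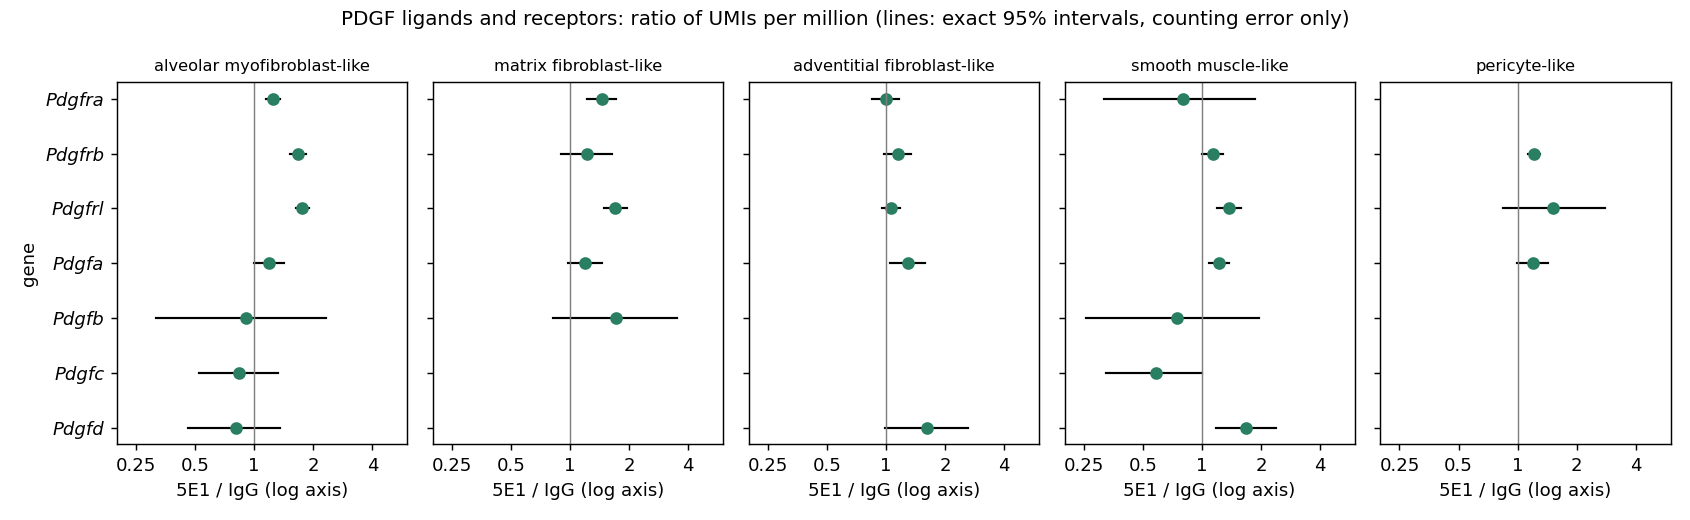
Ratio of CPM, 5E1 over IgG (log axis), for PDGF receptors and ligands in 5 mesenchymal classes, with exact 95% intervals as lines and no point for genes under 20 UMIs. Pdgfrl and Pdgfra lie above 1 in both large fibroblast classes over all cells, Pdgfra in alveolar myofibroblast-like cells not within each of their clusters, and Pdgfra lies at 1 in adventitial fibroblast-like cells.

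Across the transcriptome of alveolar myofibroblast-like cells, contractile genes were lower and elastin was higher in the 5E1 library. Acta2, which encodes smooth muscle actin, stood at 4741 CPM in the IgG and 2342 CPM in the 5E1 library, a 2.02-fold difference (1.99 to 2.06). Cnn1, the gene of calponin, was 3.19-fold (2.95 to 3.46) lower, Tpm1 2.42-fold (2.35 to 2.49) and Myocd, a coactivator that drives smooth muscle genes, 4.95-fold (3.25 to 7.88). Of the 19 contractile genes 17 were lower, with a median log2 ratio of -0.62 (-0.70 to -0.58), below all of 10000 random lists. In smooth muscle-like cells Acta2 was at 10546 CPM and 10737.5 CPM, and B cell-like cells, which should lack it, had 196 CPM and 84.4 CPM. Eln, which encodes elastin, was at 4120 CPM (4087 to 4154) and 9020 CPM (8949 to 9091), a ratio of 2.19 (2.16 to 2.21). Within clusters 12, 21 and 23 of the class the ratio of Eln was 2.11, 2.53 and 2.32, and Acta2 was 2.11-fold, 2.46-fold and 1.74-fold lower. The elastic fibre list, Eln included, was split, with 9 members higher and 10 lower, and its median of -0.08 took the other sign under median-ratio scaling. The largest part of the class fell in cluster 21 in the IgG library (46.2%) and in cluster 23 in the 5E1 library (50.0%), and cluster 12 held 30.4% and 15.2% of it.

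Among genes with at least 200 UMIs in both libraries together and at least 50 CPM in 1 of them, the lowest ratios in alveolar myofibroblast-like cells, apart from the Hedgehog targets, belonged to Egln3, an oxygen-sensing prolyl hydroxylase (5.53-fold lower in 5E1, 4.56 to 6.77), Pltp, a phospholipid transfer protein (5.33-fold, 4.48 to 6.40), Entpd1, an ectonucleotidase (4.99-fold, 4.09 to 6.13), and Adgrg2 (3.48-fold, 2.83 to 4.31). Adgrg2 lies on chromosome X, and the sex of the pooled pups differed between the libraries. Igf1, a growth factor, was at 432 CPM and 127 CPM, and Cd200 and Mdfi were 3.17-fold and 2.71-fold lower. Igf1 was also lower in several other classes, with a median log2 ratio of -1.29 over them, whereas Pltp had -0.41 and Entpd1 -0.22. The highest ratios within these limits belonged to Fmo2, a monooxygenase (5.63, 4.82 to 6.59), Stc1, a secreted glycoprotein that also leads cluster 23 (4.20, 3.83 to 4.62, and 3.73 within that cluster), Dusp5, a phosphatase of ERK kinases (3.68, 3.11 to 4.37), and Penk (3.18, 2.72 to 3.72). Mgp, an inhibitor of calcification, was at 234 CPM and 675 CPM, Vsnl1 had a ratio of 2.79 and Nr4a2 one of 2.72. Gas1, a Hedgehog co-receptor that the pathway represses, was at 25 CPM and 67.2 CPM, and the imprinted H19 at 126 CPM and 337 CPM. Foxl1, a forkhead gene known as a Hedgehog target, gave 136 UMIs in the IgG and 1 in the 5E1 library, 65.7-fold (11.6 to 2615) lower.

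Other lists in alveolar myofibroblast-like cells moved in both directions. Of 17 mesenchymal transcription factors linked to Hedgehog signalling, 16 were measured and 10 were lower, with a median of -0.24, among them Twist1 (-1.31) and Osr1 (-1.04). Wnt pathway genes had a median of -0.46 with 12 of 20 lower, among them Sfrp1 (-1.67), a secreted Wnt antagonist, while Rspo1, a Wnt agonist, had 1.55. Of 24 collagen and matrix genes 19 were lower, with a median of -0.20 (-0.32 to -0.17), although Col3a1 (0.28) and Col1a1 (0.26) were higher. The TGF-beta list had a median of -0.22 (-0.35 to -0.18) with 12 of 16 lower, among them Tgfb2 (-0.63) and Ctgf (-0.61). FGF genes had a median of 0.14 with 10 of 17 higher and Fgfr2 at -2.85. The BMP list was split into 6 higher and 6 lower, with Bmp4 at -1.14 and Id3 at 0.58.

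Immediate early and dissociation stress genes were also higher in alveolar myofibroblast-like cells of the 5E1 library, with 16 of 20 higher and a median of 0.68 (0.60 to 0.74). Btg2 had 1.52, Fos 1.28 and Fosb 1.24, whereas the heat shock gene Hspa1a (-1.31) was lower. The same list had medians of 0.49 in matrix fibroblast-like, 0.43 in pericyte-like, 0.41 in AT2-like and 0.13 in endothelial-like cells. The sex of the pooled pups differed as well. Kept cells of the IgG library held 4 UMIs of Y-linked genes (0.0517 CPM) and those of the 5E1 library 5009 (85.1 CPM), and 97.1% and 30.7% of mesenchymal cells had a UMI of Xist, the transcript of the inactive X chromosome. Restricted to 5E1 cells with an Xist and no Y-linked UMI, the contractile median was -0.77. AT2 marker transcripts such as Sftpc, which free RNA brings into fibroblasts, were lower in alveolar myofibroblast-like cells of the 5E1 library, with a median of -0.87, while AT1 markers were higher, with a median of 0.92. Markers of matrix fibroblasts had a median of -0.82 there, and haemoglobin transcripts were at 357 CPM and 1105.5 CPM.

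**Figure D3:**
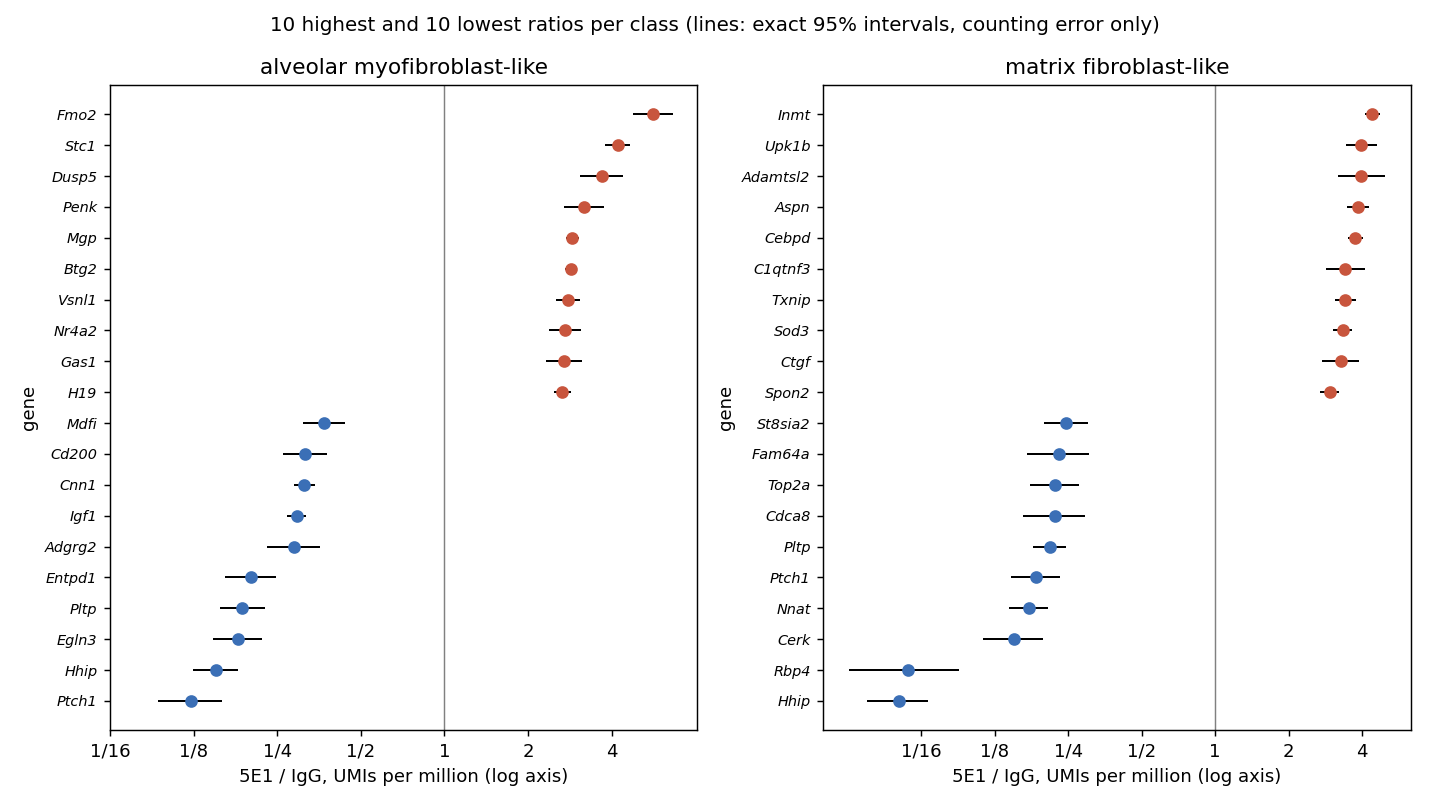
Ratio of CPM, 5E1 over IgG (log axis), of the 10 highest and 10 lowest genes by the ranking rule in each large fibroblast class, with exact 95% intervals for counting error as lines. Hhip, Ptch1 and Pltp are among the lowest in both classes, and Inmt, the top of the matrix panel, is also a gene that defines that class.

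Matrix fibroblast-like cells showed lower levels of cell division genes and higher levels of matrix genes in the 5E1 library. Top2a, a topoisomerase of dividing cells, stood at 86.6 CPM (81.2 to 92.3) in the IgG and 19.2 CPM (15.5 to 23.5) in the 5E1 library, a 4.51-fold difference (3.64 to 5.65), and Cdca8, a mitotic gene, was 4.54-fold (3.46 to 6.07) lower. All 30 genes of the G2 and M phase list were lower, with a median log2 ratio of -1.68 (-1.76 to -1.51). Eln was at 1825 CPM and 5077 CPM, a ratio of 2.78 (2.73 to 2.84), and 15 of 19 elastic fibre genes were higher with a median of 0.36 (0.27 to 0.42), among them Emilin2 (1.35), Fbn2 (0.93) and the cross-linking enzyme Lox (0.93). Cluster 19 held most of the class in both libraries, 80.4% and 53.4%, while cluster 20 held 8.50% and 40.1%. With clusters weighted alike the G2 and M phase median was -1.11, and with female 5E1 cells only it was -1.27.

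Beyond the cell cycle, Rbp4, a retinol carrier, was 18.1-fold (11.2 to 31.3) lower in matrix fibroblast-like cells of the 5E1 library, Cerk, a ceramide kinase, 6.67-fold (5.13 to 8.84), Nnat 5.79-fold (4.90 to 6.89), Pltp 4.75-fold (4.11 to 5.53) and St8sia2, a polysialyltransferase, 4.06-fold (3.35 to 4.97). The highest ratios among genes with at least 200 UMIs in both libraries together and at least 50 CPM in 1 of them, apart from Inmt, belonged to Upk1b (3.98, 3.47 to 4.57), Adamtsl2, which binds fibrillin microfibrils (3.96, 3.21 to 4.91), Aspn, a small matrix proteoglycan (3.85, 3.50 to 4.23), and Cebpd, a transcription factor of fat and stress responses (3.76, 3.53 to 4.01). Txnip had a ratio of 3.42, Sod3, an extracellular antioxidant enzyme, 3.34, Ctgf, a matricellular growth factor, 3.27, and Spon2 2.95. Aspn had a log2 ratio of 1.94 here and a median of -0.35 over the other classes. Cebpd was also among the 5 highest genes of pericyte-like cells (1.23), and Txnip among those of adventitial fibroblast-like cells (1.09). Their difference is therefore not particular to this class. Rspo1 gave 30 and 153 UMIs, a ratio of 11.6 (7.83 to 17.8). It was also higher in alveolar myofibroblast-like cells and in adventitial fibroblast-like cells, with a log2 ratio of 1.41 in the latter. Upk1b and Rspo1 are also mesothelial markers, and Msln, a further one, had a log2 ratio of 0.77 in these cells that came to 0.07 without the cell of each library with most Msln UMIs.

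The TGF-beta and collagen lists, lower in alveolar myofibroblast-like cells, were higher in matrix fibroblast-like cells, a difference between classes that was not tested. The TGF-beta list had a median of 0.24 (0.09 to 0.34) with 11 of 16 members higher, and the collagen and matrix list one of 0.10 (0.06 to 0.17) with 17 of 24 higher, among them Dcn (0.83) and Sparc (0.52). Lipid handling genes had a median of 0.35 (0.22 to 0.44) with 12 of 14 higher, led by Zbtb16 (2.64) and Fabp4 (1.12). Retinoic acid genes had a median of 0.35 with 7 of 12 higher, among them Cyp26b1 (1.53) and Aldh1a1 (1.32), whereas Rbp4, of the same list, had -4.14. Contractile genes were lower here too, with a median of -0.31 (-0.42 to -0.19) and 15 of 18 lower, which came to -0.16 without called doublets. Hedgehog-linked transcription factors had a median of -0.34 with 12 of 15 lower, among them Foxl1, at 79 and 2 UMIs (17.3-fold lower, 4.63 to 145), and Mycn (-2.12). AT2 markers were lower in these cells as well, with a median of -0.54, and haemoglobin transcripts stood at 1076 CPM and 2953 CPM.

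Cell division was compared across all classes, since the septal mesenchyme is growing at this age. The share of matrix fibroblast-like cells with 2 or more UMIs of G2 and M phase genes, at 1000 UMIs per cell, was 16% (14.5 to 17.6%) in the IgG and 8.44% (6.81 to 10.3%) in the 5E1 library, with 3 or more UMIs 11.3% and 3.14%, and with 1 or more 38.9% and 32.6%. Among alveolar myofibroblast-like cells the shares were 26.5% (24.7 to 28.5%) and 17.3% (15.1 to 19.6%). At 2 or more UMIs they were also lower in interstitial macrophage-like (22.5% and 13.2%), pericyte-like (26.9% and 18.1%), smooth muscle-like (17.5% and 11.8%) and endothelial-like cells (30.4% and 24.6%), and in the remaining classes the interval of the ratio included no difference. In these 4 classes it also included no difference without thinning, in all but smooth muscle-like cells with 1 or more UMIs, and in interstitial macrophage-like and smooth muscle-like cells with 3 or more. The interval of a ratio of shares is too wide where shares are large, as without thinning or with 1 or more UMIs. That it included no difference there does not show that the shares were alike. Of the remaining classes, AT2-like cells were lower with 1 or more (ratio interval 0.628 to 0.978) and with 3 or more UMIs (0.339 to 0.891). Without thinning, B cell-like cells (1.08 to 1.64) and cluster 3 (1.02 to 1.45) were higher, but both were deeper in the 5E1 library, which raises unthinned shares. Their median depths were 2498.5 and 3325 UMIs in B cell-like cells and 2415 and 2857 UMIs in cluster 3. At 1000 UMIs per cell and 2 or more UMIs of the list, cluster 3 gave 29.8% and 26.0%, with a ratio interval of 0.663 to 1.15. Thinned, with 2 or more UMIs, B cell-like cells gave 16.3% (12.7 to 20.4%) and 20.4% (16.7 to 24.6%). B cells can divide, so these shares are not a background for the others. Unthinned shares were 52.3% and 46.5% in matrix and 61.1% and 52.6% in alveolar myofibroblast-like cells. The list's summed level was 1984 CPM and 747 CPM in the first class and 3180.2 CPM and 2416 CPM in the second, where 29 of 30 members were lower with a median of -0.47. With female 5E1 cells only that median was -0.10. Division genes such as Ccnb1 are among the leading genes of cluster 12, which held 30.4% and 15.2% of the class, and with clusters weighted alike, which fixes that share, the median took the other sign at 0.21. S phase genes had medians of -0.83 in matrix and -0.43 in alveolar myofibroblast-like cells, with all 26 lower in the second. Outside these classes the G2 and M phase median was -0.55 in AT2-like and -0.41 in endothelial-like cells, each with all 30 members lower, 0.12 in adventitial fibroblast-like and 0.74 in mesothelial-like cells.

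Interferon-response genes were lower in the 5E1 library in several classes outside the fibroblasts. In endothelial-like cells Igtp, an interferon-induced GTPase, was at 184 CPM (176 to 193) in the IgG and 13.6 CPM (11.6 to 15.8) in the 5E1 library, a 13.6-fold difference (11.5 to 16.1). Iigp1 and Gbp2, which also encode interferon-induced GTPases, were 6.29-fold (5.72 to 6.92) and 6.18-fold (5.43 to 7.06) lower, and the antigen presentation genes H2-Q7 and Tap1 6.16-fold and 5.04-fold. All 18 measured members of the type I interferon list were lower in endothelial-like cells, with a median of -1.22 (-1.38 to -1.07), and all 18 in monocyte-like cells, with a median of -2.30 (-2.62 to -1.95). In monocyte-like cells Isg15 was 6.31-fold (4.96 to 8.16) and Oasl2 7.22-fold (4.79 to 11.4) lower, although some genes that define this class respond to interferon too. The medians were -1.33 in B cell-like, -1.12 in interstitial macrophage-like, -1.09 in neutrophil-like, -0.85 in matrix fibroblast-like and -0.19 in adventitial fibroblast-like cells. In alveolar myofibroblast-like and mesothelial-like cells they were -0.41 and -0.50, although the summed CPM of the list was higher in the 5E1 library there, at 856 CPM and 957 CPM and at 2368 CPM and 2570 CPM. In matrix fibroblast-like cells the sums were 1016 CPM and 938 CPM. Restricted to female 5E1 cells, the median was -1.30 in endothelial-like and -2.37 in monocyte-like cells.

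In AT2-like cells, genes of the AT1 type were higher in the 5E1 library. All 12 AT1 markers were higher there, with a median of 0.67 (0.55 to 0.76), among them Rtkn2, at 35.7 CPM (30.7 to 41.4) and 79.5 CPM (71.3 to 88.4), Clic5 (a ratio of 2.02, 1.71 to 2.40) and Hopx (1.99, 1.84 to 2.14). Scnn1g and Scnn1a, subunits of the epithelial sodium channel, had ratios of 2.66 (2.13 to 3.35) and 2.27 (1.88 to 2.76), and Rgcc one of 2.36 (2.11 to 2.65). Mdk, a growth factor, was 2.33-fold (1.97 to 2.75) lower, and Hdc and Tyms 2.04-fold and 1.96-fold. The 17 genes of surfactant and lipid synthesis were split into 10 higher and 7 lower, with a median of 0.02 (-0.04 to 0.10), and Sftpc, the surfactant protein C gene, had a log2 ratio of -0.16. In AT1-like cells the AT1 markers had a median of 0.01. The AT1 marker median in AT2-like cells was 0.41 with female 5E1 cells and 0.26 with cells thinned to 1000 UMIs. In the clustering made anew, cluster 25, the richer in AT1 markers, took 8.48% and 15.4% of these cells and cluster 7 took 89.7% and 82.1%, and the median was 0.10 and 0.25 within them.

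**Figure D4:**
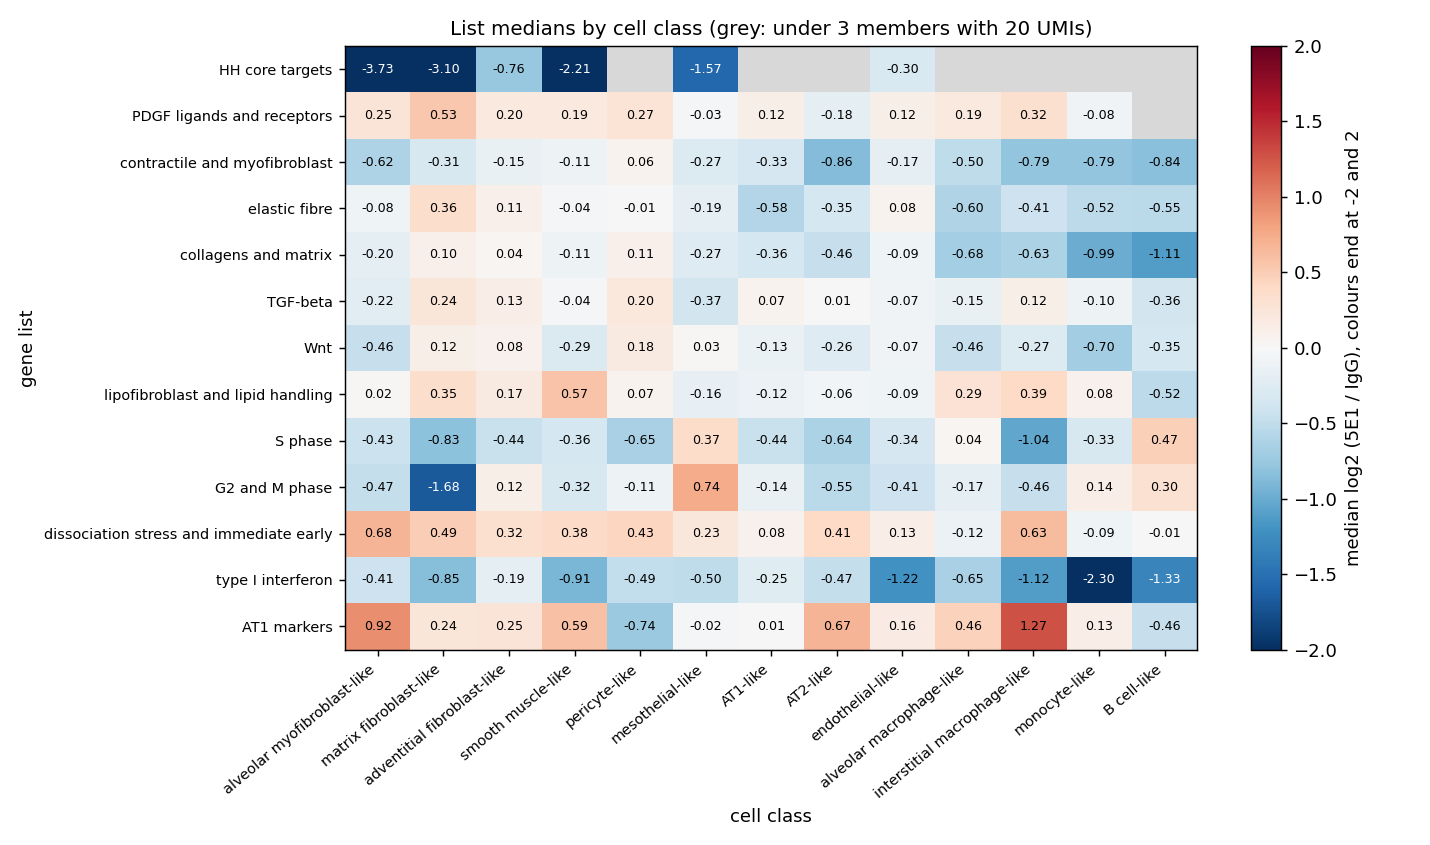
Median log2 ratio, 5E1 over IgG, of 13 gene lists in 13 cell classes, with the value in each cell and grey where fewer than 3 members reached 20 UMIs. Hedgehog targets are lowest in both large fibroblast classes, G2 and M phase genes in matrix fibroblast-like cells (-1.68), and type I interferon genes in monocyte-like (-2.30), B cell-like (-1.33) and endothelial-like (-1.22) cells, while the elastic fibre median of alveolar myofibroblast-like cells (-0.08) turns positive under median-ratio scaling.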

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

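Among the tests here, the one for a small group of AT1-like cells within the AT2-like class was set down before its result was seen, and all others were chosen only after the result was seen. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d, left out of the ranking of genes, gave 85.1 CPM in kept cells of the 5E1 library and 0.0517 CPM in those of the IgG library. The 5E1 pool thus held male pups and the IgG pool held almost no male cells. List medians drew attention where the large fibroblast classes went opposite ways. For collagens and matrix genes the median log2 ratio of the matrix fibroblast-like class lay 0.30 above that of the alveolar myofibroblast-like class (0.10 and -0.20). For the TGF-beta list it lay 0.46 above (0.24 and -0.22). Neither difference between classes was tested.

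Interferon-response genes such as Igtp and Isg15 were lower in endothelial-like and monocyte-like cells of the 5E1 library. Sex make-up is argued against as the whole cause, since the endothelial-like median was -1.30 with female 5E1 cells and -1.22 with all, and free RNA too, since the difference in summed CPM of the list was 6.48 times that of the median class in endothelial-like cells (1795 CPM against 277 CPM) and 19.4 times in monocyte-like cells. A difference between the pools other than the antibody, such as an infection or a litter, may also be the cause. Male and female 5E1 cells differed by -0.0077 (-1.30 in each), but with 1 pool per antibody this source and the antibody cannot be told apart. An effect of Hedgehog blockade on interferon signalling remains an open hypothesis.

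G2 and M phase genes such as Top2a were lower in matrix fibroblast-like cells of the 5E1 library. The median of -1.68 came to -1.27 with female 5E1 cells and to -1.11 with clusters weighted alike. Sex and cluster make-up may each carry a part, but neither alone accounts for most of it in these tests. No test applied both restrictions together, so their joint part is unknown. Female 5E1 cells come from only some of the pooled pups, so sex and pup cannot be told apart. A lower level in every class is argued against as well, since the lowest median among 12 classes outside the mesenchyme was -0.55 and the highest 0.30. In alveolar myofibroblast-like cells the median of -0.47 lay within that range and was -0.10 with female 5E1 cells and 0.21 with clusters weighted alike, which fixes the share of cluster 12 with its division genes, so sex and cluster make-up stay open there, and a shift shared with other classes and an effect within this class cannot be told apart. A lower rate of division of matrix fibroblast-like cells after Hedgehog blockade is a candidate explanation that 1 pool per antibody leaves untested.

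AT1 markers such as Hopx and Rtkn2 were higher in AT2-like cells of the 5E1 library, with a median of 0.67. Free RNA is argued against as the whole cause, since the rise in their summed CPM was 8.07 times the highest rise outside the epithelium (1613 CPM against 199.8 CPM in smooth muscle-like cells), and sex make-up too, since the median was 0.41 with female 5E1 cells. Within cluster 7 of the new clustering it was 0.25, but cluster 25, with 12763 CPM of these markers against 2445 CPM in cluster 7 of the IgG library, was split off in part by them, so a group of cells near AT1 and a shift of the whole class cannot be told apart. Without the 10% of cells richest in the markers the log2 ratio of their sum was 0.58 against 0.47, which does not exclude such a group, since cluster 25 held 15.4% of the class in the 5E1 and 8.48% in the IgG library. Doublets (0.66 without called ones, a call that takes 41.3% and 32.2% of simulated doublets), depth (0.35 for the sum and 0.26 for the median after thinning) and other differences between the pools stay open too.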

How the results depend on the processing

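Comparisons with female 5E1 cells, with clusters weighted alike, with reporter cells and without the top cell were chosen only after the results were seen, and the others were fixed before. No paired analysis was possible because each condition has 1 library. Of 207 alternatives of the main results, 167 stayed within the counting interval, 35 moved outside it and 5 took the other sign where the main interval lay wholly above or below 0. For named genes these were 1536, 257 and 8 of 1801. The cause was not tested for any of the values below, all log2 ratios. Gli1 in the 5E1 library had only 3 and 4 UMIs in the large fibroblast classes. Pdgfrb in endothelial-like cells changed sign with thinning and also with female 5E1 cells. Scaling moved the median of all genes by at most -0.08, in alveolar myofibroblast-like cells. Shares of immune classes have no value among non-immune cells, and classes of 1 cluster none with clusters weighted alike.

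With median-ratio scaling alveolar myofibroblast-like cells had contractile -0.54, elastic fibre 0.0027 (sign changed) and G2 and M phase -0.39. With the mean over cells they had elastic fibre 0.030 (sign changed) and G2 and M phase -0.54, and contractile in matrix fibroblast-like cells was -0.42. Without doublets the last was -0.16, and Mgp in B cell-like cells took the other sign at 0.065. Thinning to 1000 UMIs gave Hedgehog targets -2.50 in alveolar myofibroblast-like and -1.48 in smooth muscle-like cells, PDGF 0.80 in alveolar myofibroblast-like and 0.73 in matrix fibroblast-like cells, AT1 markers in AT2-like cells 0.26 and, with changed sign, elastic fibre in alveolar myofibroblast-like cells 0.077, Ptch1 in endothelial-like cells 0.092 and Pdgfrb there -1.07. A minimum of 100 UMIs gave Hedgehog targets -3.03 and PDGF 0.53 in alveolar myofibroblast-like cells. With 5 UMIs added, Hedgehog targets had -2.81 in alveolar myofibroblast-like and -2.51 in matrix fibroblast-like cells, and interferon in monocyte-like cells -1.75.

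With female 5E1 cells, alveolar myofibroblast-like cells had Hedgehog targets -2.90, contractile -0.77 and G2 and M phase -0.10, matrix fibroblast-like cells had G2 and M phase -1.27 and AT2-like cells had AT1 markers 0.41. Signs changed for Pdgfrb in endothelial-like cells (-0.41), Cd300ld in monocyte-like cells (-0.16) and Ly6e in cluster 3 (0.24). With clusters weighted alike, alveolar myofibroblast-like cells had contractile -0.70 and, with changed sign, elastic fibre 0.12 and G2 and M phase 0.21, where equal weights fix the share of cluster 12, led in part by division genes. With these weights matrix fibroblast-like cells had G2 and M phase -1.11, and Pdgfrb in smooth muscle-like cells changed sign (-0.071). With reporter cells G2 and M phase in alveolar myofibroblast-like cells was -0.39. Without the top cell Pdgfa in neutrophil-like cells changed sign (0.088).

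Ratios of cell shares with female cells only were -0.31 for mesenchyme, 0.70 for endothelial-like and 0.65 for alveolar macrophage-like cells, and -0.17 for AT2-like cells, where the sign changed from 0.058, a value whose interval included no difference. With cells of either sex, ratios of shares among non-immune cells were -0.30 for mesenchyme, 0.50 for epithelium and 0.66 for endothelial-like cells. Ratios of shares of cycling cells were -0.32 in alveolar myofibroblast-like and -0.26 in matrix fibroblast-like cells with 1 or more UMIs, -1.85 in matrix fibroblast-like cells with 3 or more, and -0.21 and -0.17 in these classes without thinning.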

Other observations

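No test is reported here, and which lists and genes to print was chosen after their values were seen. The reporter cassette gave 45676 UMIs in the IgG and 24050 in the 5E1 library. At 1000 UMIs per cell it was detected in 54.3% and 45.8% of alveolar myofibroblast-like cells, 52.6% and 41.5% of matrix fibroblast-like cells and 69.1% and 67.4% of adventitial fibroblast-like cells, against 9.33% and 6.34% of B cell-like cells. Without thinning these were 75.6% and 63.6%, 71.9% and 58.3%, 88.2% and 85.5%, and 21.6% and 21.1%. The IGF list holds growth factors, their receptors and binding proteins, and H19. It had a median log2 ratio of 0.24 in matrix fibroblast-like cells with 8 of 11 higher. It was led by the binding protein genes Igfbp6 (1.60) and Igfbp3 (1.45), whereas the growth factor Igf1 had -1.59. The Hedgehog co-receptor Gas1 was higher in these cells (1.21), as was Scube2 (1.35), a carrier of the ligand and a leading gene of cluster 20, which held 8.50% and 40.1% of the class, although the list of ligands, co-receptors and transducers had a median of -0.17. Angpt2, an angiopoietin, was lower (-1.67), as was the cell cycle inhibitor Cdkn1a (-1.13). BMP genes had a median of 0.30 in matrix fibroblast-like cells with 8 of 10 higher. The secreted Wnt antagonist Sfrp1, lower in alveolar myofibroblast-like cells, had 1.77 here.

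Cells outside the fibroblasts differed in their own ways. Endothelial-like cells of the 5E1 library had more Hey1, a Notch target (a ratio of 1.78, 1.64 to 1.93), and more Vwf (1.67, 1.58 to 1.75), while the new clustering put 158 and 202 cells in an arterial and 95 and 55 in a lymphatic cluster, so the make-up of the class differs too. In endothelial-like cells 9 of 13 Notch genes were higher with a median of 0.14. Alveolar macrophage-like cells had Gpnmb at 89.1 CPM and 238 CPM and Cd63 at 189 CPM and 504 CPM, whereas the elastase gene Mmp12 was 2.31-fold (1.84 to 2.90) lower. Inflammatory cytokine genes had a median of 0.64 in interstitial macrophage-like cells, with 11 of 15 higher, and of -0.70 in monocyte-like cells, with 12 of 14 lower, among them Ccl5 (-4.13). Ifi47, an interferon-induced GTPase, was at 110 CPM and 7.21 CPM in monocyte-like cells. Smooth muscle-like cells had Lpar1, a receptor of lysophosphatidic acid, 9.61-fold (5.80 to 17.1) lower, and its log2 ratio of -3.22 came to -2.47 with clusters 16 and 22 of that class, 27.6% against 14.6% and 72.4% against 85.4% of it, weighted alike. In adventitial fibroblast-like cells the chemokine Ccl2 was 7.25-fold (4.92 to 11.1) lower. S phase genes were lower in interstitial macrophage-like cells, with all 24 lower and a median of -1.04, and higher in B cell-like cells, with 24 of 26 higher and a median of 0.47. Haemoglobin transcripts were lower in adventitial fibroblast-like cells of the 5E1 library, at 1107 CPM and 173 CPM, in contrast to both large fibroblast classes.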
